A study of Mus musculus with 6 samples.

How the data were processed

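RNA was measured by bulk sequencing in 6 libraries of mouse adult spinal cord neural stem cell cultures carrying a PDGFRa-GFP reporter, separated by fluorescence-activated cell sorting into GFP-positive and GFP-negative cells. Per the labels' protocols, the cultures were grown with EGF and FGF2, RNA was extracted with a column kit, and libraries were made with the SMART-Seq Stranded kit, a low-input full-length method. The submitters' processing notes name bcl2fastq 2.20.0.422, FastQC 0.11.8, MultiQC 1.9, TopHat2 2.1.1, SAMtools 1.9, featureCounts 2.0.0 and the mm39 build. The annotation, the strand setting of the counting and the handling of duplicate and multiply mapped reads are not given in the sources used here. Reads of a gene and of an overlapping antisense gene may therefore be mixed, and counts of near-identical copies are uncertain.

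The deposited table gives raw read counts per gene, per the file headers, with no normalization. Each line has a gene symbol, and most lines also have an Entrez gene number. It holds 26264 genes, of which 4856 had no count in any library. The 133 entries with a symbol and no Entrez number took 0.0404% of the counts of the GFP-negative libraries and 0.0505% of the GFP-positive ones, and were kept. Counts from a gene table hold PCR copies, so the precision that depth gives covers counting error only. Total counts per library lay between 31067850 and 45207335.

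Samples were grouped by the sorted fraction in their titles, with 3 libraries in each group. The titles also give each library a number, 314, 315 or 316, shared by a GFP-negative and a GFP-positive library; these are replicates 1, 2 and 3 here. The labels do not say whether the numbers stand for animals, cultures or sorting days, so p-values measure the spread between these samples, which may be technical. Libraries of the same group differed from each other by more than counting noise. Chi-square per degree of freedom lay between 9.83 and 34.2 over genes with a summed count of at least 20. None was therefore treated as a second sequencing run of the same library. Separate libraries of the same sample can also exceed counting noise, so repeats of a sample are not excluded. The numbers were checked for pairing: the deviations of same-numbered libraries from their group means correlated across genes at 0.218, 0.355 and 0.159, all above the limit of 0.1, and each library correlated best with its own number. The numbers were therefore taken to pair the samples. The fit without the block stayed the main one, as set before the data were examined, and the blocked value is printed beside a result where it changes a call or moves a count of calls by over 1.5 times.

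The main test was edgeR 4.0.16 (R 4.3.3) with TMM scaling, the filterByExpr filter, a quasi-likelihood F test and Benjamini-Hochberg adjustment, with adjusted p below 0.05 as the threshold. The filter left 14554 genes. The standard error of a log2 fold change is the fold change divided by the square root of its F value. CPM values are counts scaled to a common library size with TMM and were computed from the deposited counts; fold changes are GFP-positive minus GFP-negative on the log2 scale. In total, 29 gene lists were written before the data were examined. They covered oligodendrocyte precursor, committed oligodendrocyte, mature myelin, astrocyte, ependymal, neural stem cell, neuronal, microglia, endothelial, fibroblast and mural, Schwann cell and erythroid markers, S and G2/M phase genes, Notch, BMP and TGF-beta, Wnt, Hedgehog, receptor tyrosine kinase targets, immediate early and stress genes, cholesterol synthesis, interferon, glycolysis and hypoxia, extracellular matrix, ion channels and receptors, ventral, dorsal and Hox transcription factors, and mitochondrially encoded genes. Some genes stand in several lists, such as Hes5 in neural stem and Notch and Aldoc in astrocyte and glycolysis. Results of such lists are therefore not independent. The 27 lists with at least 3 tested members were tested with limma 3.58.1 camera (preset correlation 0.01, prior count 2, two-sided) and adjusted over the lists. Camera was repeated with an estimated correlation, and fry was run as an alternative.

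Named genes followed a rule set before the data were examined: Pdgfra; the 12 largest higher and 12 largest lower log2 fold changes among called genes with a mean log2 CPM of at least 3 and the same direction in all 3 same-numbered pairs; and, in each list, the 3 members with the smallest p and the called member of opposite direction with the smallest p. The rule gave 111 genes. Members named because a count was 5 or fewer, and the Notch genes Notch3 and Lfng and the precursor gene Sox10, were chosen after their values were seen where the rule did not take them. Some genes that the rule took, or that a small count would name, are not reported here.

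Alternatives set before the data were examined were RLE and upper-quartile scaling, no low-count filter, a CPM of 1 in 3 libraries, DESeq2 1.42.0, limma-voom, a replicate block, leaving out each library and each number, a log2 fold change above 1, glmTreat at 1.5-fold, camera with an estimated correlation and fry. Removal of 6 abundant genes and limma-trend with the block were added after the data were seen. So were corrections for transcript length and GC content with the block. The 6 genes were Rn45s, Malat1, Rn7sk, Rpph1, Lars2 and Gm20594. Length and GC came from the longest transcript of each gene in the GENCODE M21 annotation, joined by Entrez number, for 13395 of the 14554 tested genes (92.0%). That annotation is of an older build than mm39, so no coordinates are given. The first length and GC correction also set each library's mean deviation to 0; it was replaced by a correction that removes the trend only, and both are reported.

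The fits were tested on counts simulated from the real means and library sizes, with 200 of 14554 genes changed in each of 10 runs. The edgeR test recovered 41.6% of genes changed by 0.5 on the log2 scale, 76.6% of those changed by 1 and 95% of those changed by 2, with 8.08% false calls. Camera found the shifted set of 20 genes in 10 of 10 runs and called 3 of 190 unshifted sets. Genes were drawn independently and sets at random in these runs. They therefore do not show how often camera calls sets of correlated genes. The runs also changed far fewer genes than the 55.4% called in the data, and simulated no pairing of libraries. Recovery and the share of false calls may therefore differ in the data. In a single run DESeq2 made 24.3% false calls against 10.4% for edgeR. Figures were drawn with matplotlib 3.10.9.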

Results

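The data were gene counts of 6 bulk RNA libraries from adult mouse spinal cord neural stem cell cultures, sorted for a green fluorescent reporter of Pdgfra, the platelet-derived growth factor receptor that marks oligodendrocyte precursor cells. The study asks how such cultures produce cells of the oligodendrocyte lineage, and the design sets GFP-positive against GFP-negative cells. The GFP-positive libraries held 36846570, 45207335 and 36922473 counts in replicates 1, 2 and 3. The GFP-negative libraries held 32869705, 31148620 and 31067850.

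Pdgfra (Entrez 18595), the gene behind the sort, was read first as a check of the labels. It stood at 229 ± 21.3 CPM (SD, n = 3) in GFP-positive cells and 13.7 ± 5.62 CPM (SD, n = 3) in GFP-negative cells, a log2 fold change of 4.06 (SE 0.27, edgeR adjusted p = 1.28e-05). Each GFP-positive library lay above each GFP-negative library.

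The fractions differed in 8058 of 14554 tested genes (55.4%), with 3804 higher and 4254 lower in GFP-positive cells. On the log2 scale, 883 genes were higher and 1784 lower by more than 1. By more than 3, 60 genes were higher and 389 lower. Without replicate 3, 2450 genes were higher and 2951 lower. Higher genes made up 47.2% of the calls. That share was 62.7% with a length and GC correction that also centred each library at 0, chosen after seeing the data, where the median of all genes was 0.145. With the trend alone removed it was 47.3%.

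Of the genes taken by the rule for large fold changes, Sstr1 (Entrez 20605), a somatostatin receptor, was higher by 4.23 (SE 0.28, adjusted p = 1.18e-05), at 27.9 ± 3.74 against 1.49 ± 0.73 CPM (SD, n = 3). C1ql1 (Entrez 23829), a secreted C1q-related protein, was higher by 4.13 (SE 0.40, adjusted p = 7.47e-05). Kit, the stem cell factor receptor, was higher by 3.84, Dcx, a microtubule-binding protein, by 3.73, and Slc1a1, a glutamate transporter, by 3.71. Plppr1, Stk32a, Phactr3 and Rph3a were higher by 3.91, 3.82, 3.50 and 3.50. C1ql1, Dcx and Pdgfra stood at 14.3, 17.0 and 19.3 CPM in the GFP-negative library of replicate 2, and at up to 5.18, 7.03 and 13.9 CPM in the other GFP-negative libraries.

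On the lower side, the fold changes reached larger sizes. Lrrc32 (Entrez 434215), a tether of latent TGF-beta, was lower in GFP-positive cells, with a log2 fold change of -4.84 (SE 0.20, adjusted p = 2.16e-06), at 1.21 ± 0.40 against 35.5 ± 2.87 CPM (SD, n = 3). Itga5 and Itga7, integrin chains that bind fibronectin and laminin, had values of -4.81 and -4.55, Lamb2, a laminin chain, -4.42, Cd44, a hyaluronan receptor, -4.42, Sdc4, a heparan sulfate proteoglycan, -4.41, and Vcam1, an adhesion molecule, -4.39. Slc6a11, a GABA transporter, was at 21.6 ± 2.41 CPM in GFP-positive and 450 ± 115 CPM in GFP-negative cells (SD, n = 3). Mamdc2, Enpep, Celsr1 and Ctsc had values of -4.81, -4.78, -4.58 and -4.50.

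**Figure D1:**
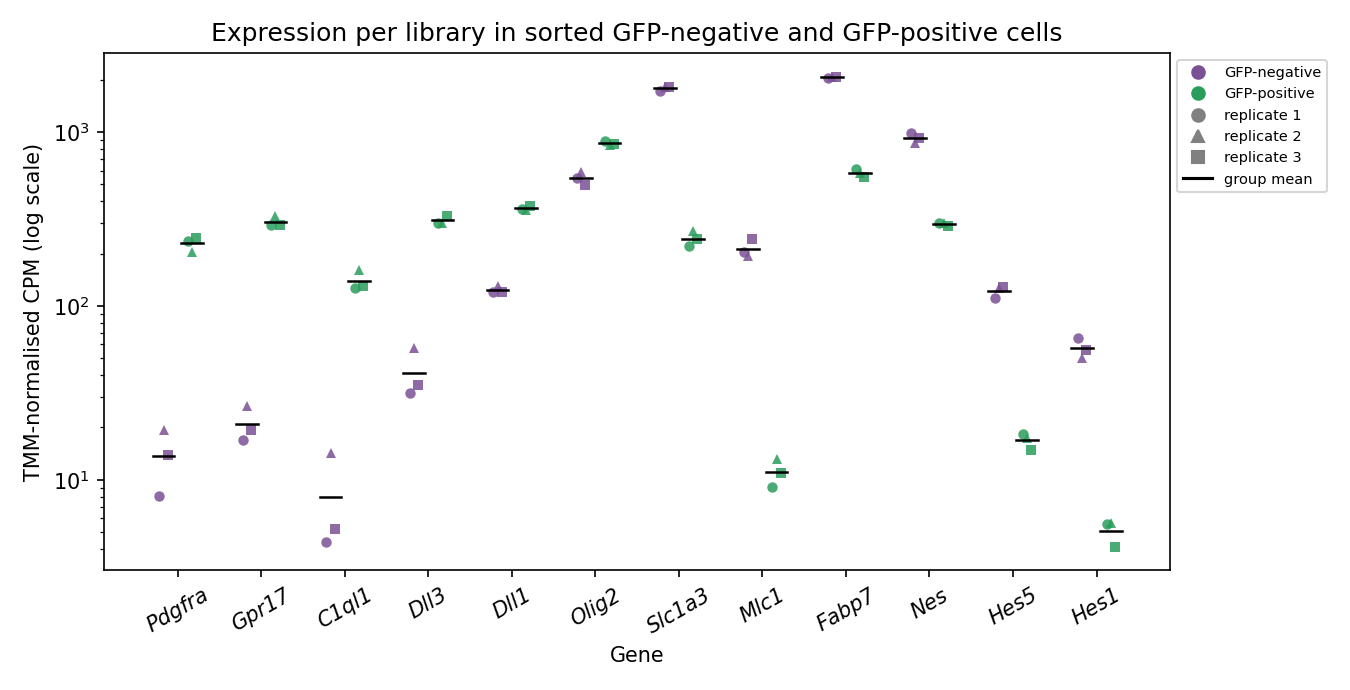
TMM-normalised CPM on a log axis for 12 named genes, with a point for each library (colour for sorted fraction, shape for replicate) and a line for each group mean (n = 3). Pdgfra, Gpr17, C1ql1, Dll3, Dll1 and Olig2 lay higher in every GFP-positive library than in any GFP-negative library, and Slc1a3, Mlc1, Fabp7, Nes, Hes5 and Hes1 lay lower.

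Oligodendrocyte precursor genes were higher in GFP-positive cells. Of 20 listed markers, with Pdgfra left out, 18 were higher and 0 lower (18 higher and 0 lower when adjusted over the list alone), with a median log2 fold change of 1.32. Without GFP-negative replicate 1, and with the length and GC trend removed, 1 was lower. The list passed camera (adjusted p = 1.70e-06), and had adjusted p = 0.246 with an estimated correlation. Gpr17, a receptor of precursors entering differentiation, was at 303 ± 21.8 against 21.0 ± 5.07 CPM (SD, n = 3), a log2 fold change of 3.85 (SE 0.16). Dll3, a Notch ligand family member, was higher by 2.92 and Lhfpl3 by 1.51. Sox10, a transcription factor of the lineage, was higher by 3.28 and varied among the replicates, at 39.4, 93.6 and 45.4 CPM in GFP-positive and 2.33, 12.5 and 3.53 CPM in GFP-negative cells.

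Genes listed for later oligodendrocyte stages were called in both directions. Of 18 tested markers of committed cells, 10 were higher and 3 lower, with the same counts adjusted over the list alone and a median of 0.40. Camera gave adjusted p = 0.0236, and adjusted p = 0.302 with an estimated correlation. Lims2, Mycl and Tns3 were higher by 3.53, 1.24 and 1.23, while Itpr2, Cemip2 and Tcf7l2 were lower, with values of -1.36, -0.44 and -0.36. Tcf7l2 lost its call without replicate 3 (adjusted p = 0.0647). Of 11 tested mature myelin markers, 4 were higher (Fa2h, Mbp, Cldn11 and Ugt8a) and 6 lower, with the same counts adjusted over the list alone, and the list did not pass camera (adjusted p = 0.367; estimated correlation p = 0.479). The lower members included Trf, which encodes transferrin, at -4.12, Aspa at -4.08 and Cryab, a small heat shock protein, at -2.15. Aspa had few counts, at a mean of 0.129 against 2.21 CPM. Anln, another lower member, is also in the G2/M list. Mbp stood at 7.56 ± 4.43 CPM in GFP-positive cells (SD, n = 3), and 11 of the 22 listed myelin genes did not pass the count filter.

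Astrocyte genes were lower in GFP-positive cells: 21 of 23 tested members were lower and 1 higher (22 lower and 1 higher adjusted over the list alone), with a median of -2.94. The camera adjusted p was 6.56e-08, with adjusted p = 0.246 with an estimated correlation. Slc1a3, a glutamate transporter, was at 244 ± 22.8 against 1792 ± 52.1 CPM (SD, n = 3), Mlc1 at 11.1 ± 2.04 against 214 ± 25.1 CPM and Hepacam, an adhesion protein, at 38.1 ± 4.05 against 293 ± 31.9 CPM. Sox9 was the higher member, by 0.34 (adjusted p = 0.0302), and lost its call in 5 of 9 fits that left out a library or a number (adjusted p up to 0.151).

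Neural stem cell genes were also lower. Of 22 tested members, 16 were lower and 2 higher, over all genes and adjusted over the list alone, with a median of -1.67. Without GFP-negative replicate 2, 4 were higher. In camera the adjusted p was 7.66e-05, and adjusted p = 0.185 with an estimated correlation. Fabp7, a fatty acid binding protein of radial glia, was at 582 ± 30.7 against 2064 ± 22.4 CPM (SD, n = 3) and Nes, an intermediate filament, at 294 ± 6.59 against 926 ± 64.9 CPM. Sox3, a transcription factor, was among the higher members, at 0.80. Of 13 tested ependymal genes, 8 were lower and 0 higher, or 9 lower adjusted over the list alone (median -1.37, camera adjusted p = 0.00457, and adjusted p = 0.248 with an estimated correlation). Among them were Foxj1, the regulator of motile cilia, at -1.44, Rfx2 at -2.62 and Tm4sf1 at -3.99. Without replicate 1, and without replicate 3, the count was 5. The other 12 of the 25 listed ependymal genes were below the filter, at 0.708 CPM or less in every library.

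**Figure D2:**
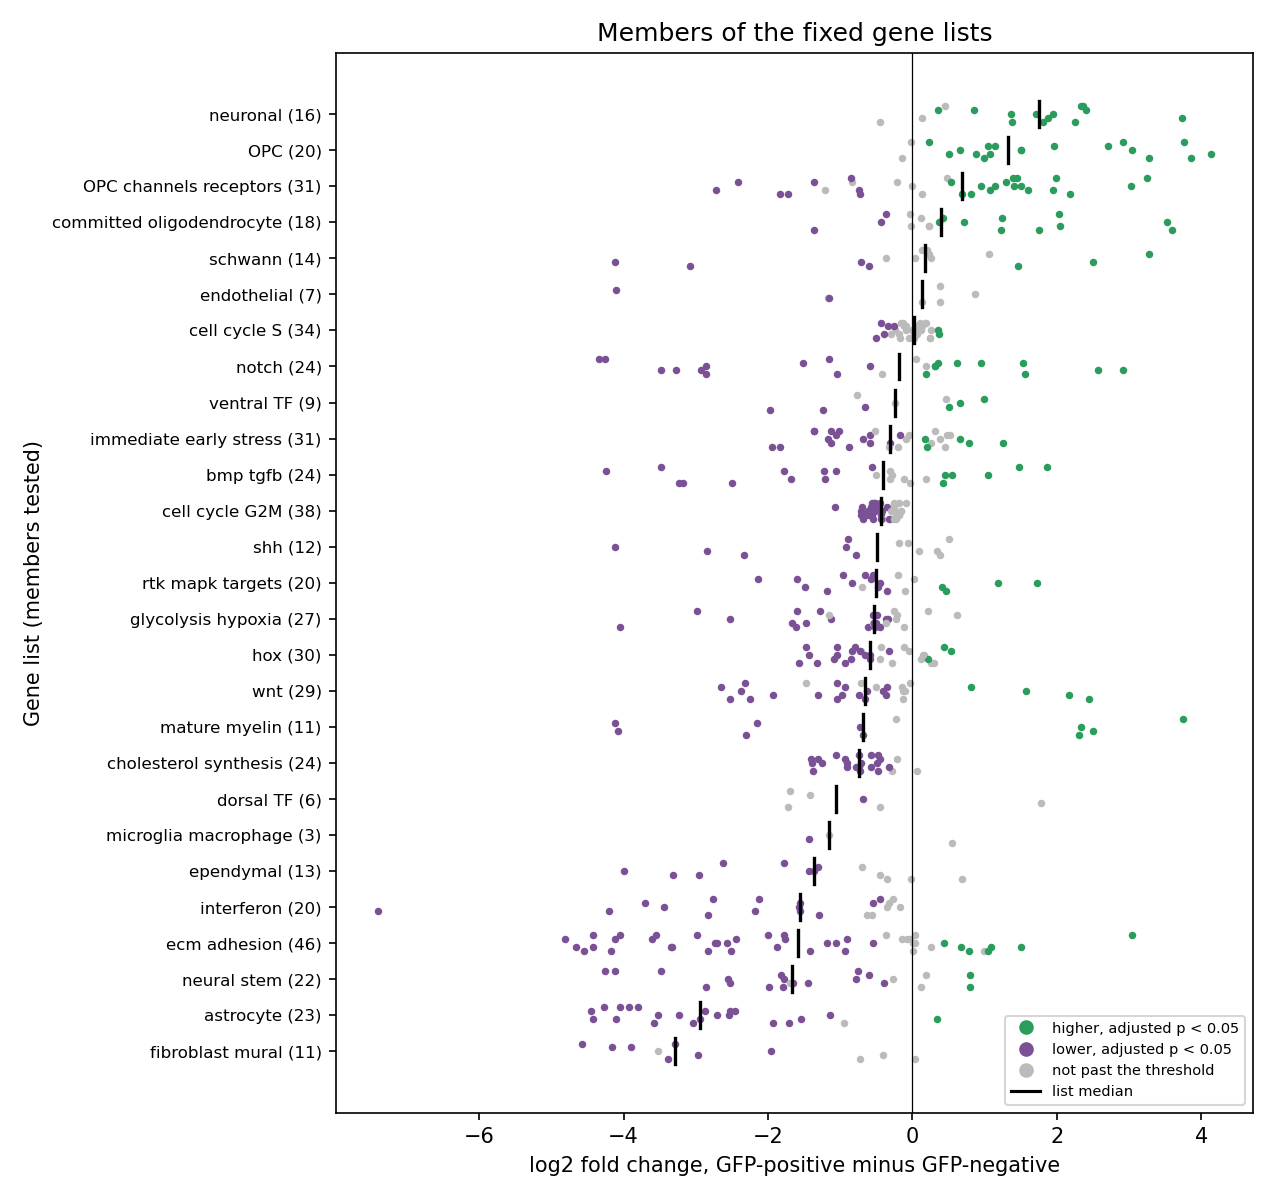
Log2 fold change of each tested member of the 27 tested gene lists, with lists ordered by their median (black bar) and the number of tested members in brackets. Green and purple points passed adjusted p below 0.05 as higher or lower in GFP-positive cells and grey points did not; the leftmost point is Ifi44, which had no count in GFP-positive cells, so that its plotted fitted value is no bound. The neuronal and oligodendrocyte precursor medians lie at the top, at 1.76 and 1.32, and the astrocyte and fibroblast medians at the bottom, at -2.94 and -3.29.

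Genes listed as neuronal were higher in GFP-positive cells. Of 16 tested members, 13 were higher and 0 lower, over all genes and adjusted over the list alone, with a median of 1.76. The camera test gave adjusted p = 2.08e-05, and adjusted p = 0.259 with an estimated correlation. Map2, a microtubule-associated protein, was at 4232 ± 272 against 1640 ± 134 CPM (SD, n = 3), Celf3, an RNA-binding protein, was higher by 2.25 and Nefm, a neurofilament chain, by 2.33. Stmn2, Slc17a6 and Slc32a1, transcripts of neurons, stood at 0.217 CPM or less in each GFP-positive library and were singled out after their values were seen.

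Ion channels and transmitter receptors differed in either direction. Of 31 tested members, 17 were higher and 8 lower, over all genes and adjusted over the list alone, with a median of 0.68. Camera called the list with adjusted p = 0.0273, against adjusted p = 0.407 with an estimated correlation. The call was lost with the replicate block (adjusted p = 0.0639) and without replicate 1 (0.0528). Grik2, a kainate receptor subunit, was higher by 1.30 and Grin1, an NMDA receptor subunit, by 2.18, while Gabra2, a GABA-A receptor subunit, had a value of -1.84.

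Notch pathway genes differed in either direction. Of 24 tested members, 10 were higher and 11 lower, with the same counts adjusted over the list alone, a median of -0.19 and a mean of -0.71. The list did not pass camera, which compares it with other genes (adjusted p = 0.647), and passed fry, which does not (0.00377). Dll1, a Notch ligand, was at 364 ± 9.02 CPM in GFP-positive and 123 ± 6.31 CPM in GFP-negative cells (SD, n = 3), a log2 fold change of 1.56 (SE 0.06, adjusted p = 1.79e-06). Hes5 and Hes1, transcriptional repressors induced by Notch, had values of -2.85 (SE 0.10) and -3.48 (SE 0.15), with adjusted p of 1.64e-06 and 2.34e-06. Notch3, a receptor, and Lfng, a modifier of the receptors, had values of -4.33 and -4.25.

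**Figure D3:**
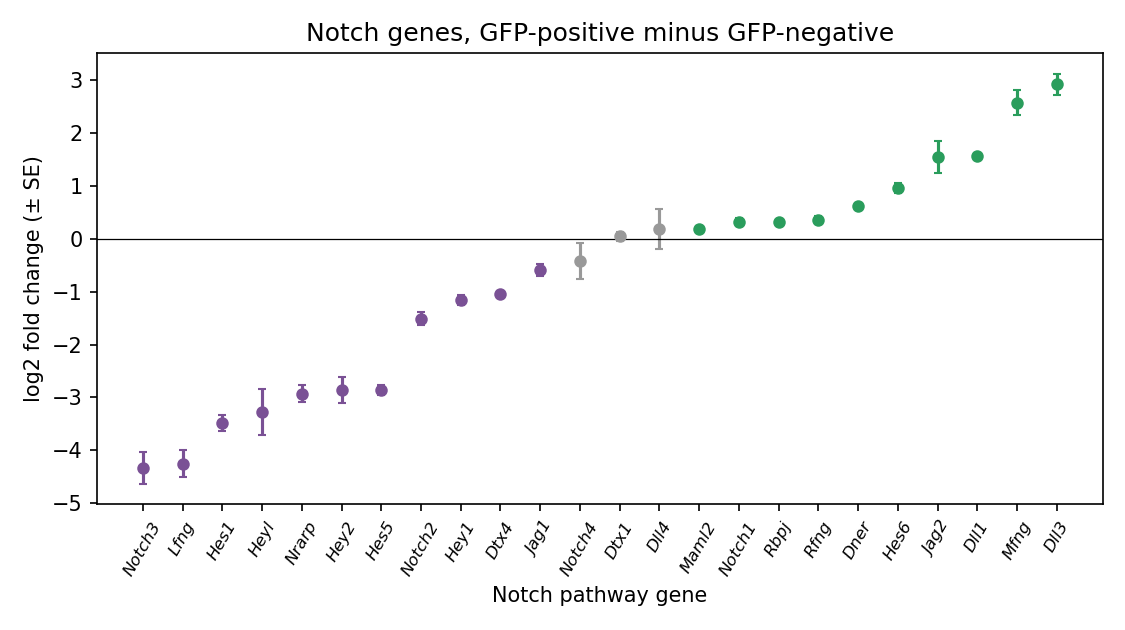
Log2 fold change of the 24 tested Notch pathway genes, ordered by value, with bars of 1 SE. Green and purple points passed adjusted p below 0.05 and grey points did not; the 10 higher genes run up to Dll3 at 2.92 and the 11 lower ones down to Notch3 at -4.33.

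Other signalling lists had more lower than higher members. Of 29 tested Wnt genes, 17 were lower and 4 higher, over all genes and adjusted over the list alone (median -0.65, camera adjusted p = 0.00515, and adjusted p = 0.185 with an estimated correlation). The receptor Fzd1 had a value of -2.25 and the ubiquitin ligase Znrf3 one of -0.93. The 4 higher members were Nkd2, Rnf43, Sfrp1 and Lgr5, at 2.44, 2.16, 1.58 and 0.81. Sfrp1 lost its call in 6 of 9 fits that left out a library or a number (adjusted p up to 0.114). Of 24 BMP and TGF-beta genes, 11 were lower and 6 higher, over all genes and adjusted over the list alone (median -0.41, camera adjusted p = 0.0312, and adjusted p = 0.441 with an estimated correlation). That call was lost with the replicate block (adjusted p = 0.0558), without GFP-negative replicate 2 (0.17) and without replicate 2 (0.134). Bmpr1b, a BMP receptor, and Id3, a BMP target, had values of -3.18 and -3.23, and Id2 was higher by 1.86. Of 12 Hedgehog genes, 6 were lower and 0 higher, over all genes and adjusted over the list alone (camera adjusted p = 0.139), with the transcription factor Gli3 at -2.85 and the transducer Smo at -0.78. With the replicate block 1 was higher, 2 were without GFP-negative replicate 2 or without replicate 2, and 3 with the correction centred at 0.

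Targets of receptor tyrosine kinases were lower in 12 and higher in 4 of 20 genes, over all genes and adjusted over the list alone, with a median of -0.51. The list missed the threshold in camera (adjusted p = 0.0915, and adjusted p = 0.621 with an estimated correlation). It passed with the replicate block (0.0487) and without GFP-positive replicate 1 (0.049). The transcription factor Etv4 had a value of -2.13. The higher members were Etv1, Myc, Ets1 and Spred3, at 1.73, 1.18, 0.46 and 0.40.

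G2/M genes were lower in GFP-positive cells, and the S phase list did not pass camera. Of 38 G2/M genes, 23 were lower and 0 higher (25 lower adjusted over the list alone; 15 without replicate 1), with a median of -0.44. Camera called it with adjusted p = 7.66e-05, against adjusted p = 0.621 with an estimated correlation. Ccnb2, a mitotic cyclin, was at 20.4 ± 1.05 against 42.9 ± 6.03 CPM (SD, n = 3), and Tacc3 and Anln had values of -0.69 and -0.68. Of 34 S phase genes, 5 were lower (Cdca7, Gins2, Rfc2, Uhrf1 and Pcna) and 2 higher (Mcm7 and Nasp), with 4 lower and 2 higher adjusted over the list alone, and a median of 0.016 with a mean of -0.024 (camera adjusted p = 0.95). The S phase counts depended on the setting. With the correction centred at 0, 14 were higher and 2 lower, against 0 higher and 22 lower of the G2/M genes, and 4 were higher with the trend alone removed. Without GFP-negative replicate 2, 7 were higher and 4 lower, and without replicate 2, 5 and 6. Without GFP-negative replicate 3, 8 were lower, and without GFP-positive replicate 1, 3 were. Without replicate 1, 1 was higher and 2 lower, and without replicate 3, 1 was higher. Of the 7 genes, Pcna lost its call in 7 of 9 fits that left out a library or a number (adjusted p up to 0.26), Gins2 and Mcm7 in 2 each (up to 0.142 and 0.084), and Cdca7 and Uhrf1 in 1 each (0.0513 without replicate 3 and 0.0604 without replicate 1).

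Metabolic lists were lower in GFP-positive cells. Of 24 cholesterol synthesis genes, 21 were lower and 0 higher, over all genes and adjusted over the list alone (median -0.73, camera adjusted p = 7.66e-05, and adjusted p = 0.479 with an estimated correlation). Hmgcs1, an early enzyme of the pathway, was at 276 ± 38.8 against 683 ± 128 CPM (SD, n = 3). Of 27 glycolysis and hypoxia genes, 18 were lower and 0 higher, or 19 lower adjusted over the list alone (median -0.53, camera adjusted p = 7.66e-05, and adjusted p = 0.441 with an estimated correlation). The glycolytic enzymes Aldoc, Aldoa and Gpi1 had values of -2.53, -1.47 and -1.28. Of the glycolysis and hypoxia genes, 1 was higher without GFP-negative replicate 2 and in the limma fits with the block, and 1 cholesterol gene was higher with the correction centred at 0.

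Interferon-response genes were lower as well, in 14 of 20 tested members with 0 higher and 16 lower adjusted over the list alone. The median was -1.56, with a camera adjusted p of 2.08e-05 and adjusted p = 0.185 with an estimated correlation. B2m, the light chain of MHC class I, was at 19.1 ± 1.85 against 46.8 ± 1.85 CPM (SD, n = 3), and the RNA sensors Ifih1 and Ddx58 had values of -3.44 and -1.58. Ifi44 had 0 counts in GFP-positive and 56 in GFP-negative cells, so it was at least 23.3-fold lower against a floor of 3 counts over the group. The list median was -1.56 with this bound as well. Bound and fitted value both lie below the median, so this could not have come out otherwise. Of 46 extracellular matrix and adhesion genes, 29 were lower and 7 higher, over all genes and adjusted over the list alone (median -1.59, camera adjusted p = 1.40e-04, and adjusted p = 0.246 with an estimated correlation). Sparc, a matrix glycoprotein, was at 39.2 ± 3.25 against 476 ± 94.8 CPM (SD, n = 3) and the laminin chain Lama5 had a value of -2.98, while Tnr, a tenascin of the oligodendrocyte lineage, was higher by 3.04.

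Patterning genes differed in part. Of 30 tested Hox genes, 16 were lower and 3 higher, over all genes and adjusted over the list alone (median -0.59, camera adjusted p = 0.0284, and adjusted p = 0.246 with an estimated correlation). The call was lost after the length and GC correction with the block (0.0899), where 6 were higher, and 8 were with the correction centred at 0. Hoxb2 had a value of -1.57. The higher members Hoxa7, Hoxd9 and Hoxd3 lost their calls in 4, 6 and 9 of 9 fits that left out a library or a number (adjusted p up to 0.108, 0.226 and 0.21), and Hoxd3 also with the replicate block (0.0668). Of 9 ventral factors, 3 were higher and 3 lower (Dbx2, Nkx6-2 and Irx3), over all genes and adjusted over the list alone. The 3 higher factors, Nkx2-2, Olig2 and Olig1, are also in the precursor list. The median of the ventral list was -0.24 while camera gave the upward direction, with adjusted p = 0.95. With the replicate block 5 were lower. Nkx6-2 lost its call in 7 of 9 such fits (adjusted p up to 0.292). Of 6 dorsal factors, 1 was lower, over all genes and adjusted over the list alone (Msx1, at -0.69; its call was lost in 4 of 9 such fits, with adjusted p up to 0.138), and 4 were lower with the replicate block (camera adjusted p = 0.819). Without GFP-positive replicate 2, and without replicate 2, 2 were lower. Without GFP-negative replicate 2, and in the limma fits with the block, 1 was higher. Zic2 had a value of -1.73 (adjusted p = 0.402, 1.42e-04 with the block) and stood at 26.6 and 7.77 CPM in the GFP-negative and GFP-positive libraries of replicate 2 and at 0.583 CPM or less in the other 4. Without GFP-negative replicate 2, which leaves its GFP-positive partner unpaired, its value was 2.55, while in each of the 3 same-numbered pairs the GFP-positive library was the lower one.

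Markers of other cell types gave the following values. Of 11 tested fibroblast and mural genes, 7 were lower and 0 higher in GFP-positive cells, over all genes and adjusted over the list alone (median -3.29, camera adjusted p = 0.00327, and adjusted p = 0.185 with an estimated correlation). Fn1, which encodes fibronectin, was at 6.84 ± 2.98 against 123 ± 11.7 CPM (SD, n = 3). The other 13 of the 24 listed fibroblast and mural genes were below the filter, at 0.449 CPM or less in every library. The list median therefore leaves out most of its members. Of 14 Schwann cell genes, 3 were higher (Sox10, Mbp and L1cam) and 4 lower (Dhh, Cdh19, Pou3f2 and Pou3f1), over all genes and adjusted over the list alone (camera adjusted p = 0.923). With the length and GC trend removed 5 were higher, and 6 with the correction centred at 0. Pou3f1 lost its call in 7 of 9 fits that left out a library or a number (adjusted p up to 0.208). Of 7 endothelial genes, 2 were lower (Flt1 and Vwf) and 0 higher, over all genes and adjusted over the list alone, with a median of 0.13 and a mean of -0.67 (camera adjusted p = 0.807). Vwf lost its call without replicate 1 (0.0575) and without replicate 3 (0.0859). The other 8 of the 15 listed endothelial genes were below the filter, at 0.7 CPM or less. Of 20 microglia and macrophage genes, 17 were below the filter, at 0.449 CPM or less in every library, and the list did not pass camera (adjusted p = 0.647). Of the other 3, 1 was lower (2 without GFP-negative replicate 1 and without replicate 1), and Cd68 had a value of 0.54 (adjusted p = 0.054, 0.044 with the replicate block; 1 higher and 1 lower adjusted over the list alone). All 7 erythroid genes were below the filter, at 0.193 CPM or less. None of the 13 listed symbols of mitochondrially encoded genes was in the count table, so that list was not tested.

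Immediate early and stress genes were lower in 15 and higher in 5 of 31 tested members, over all genes and adjusted over the list alone (median -0.31, camera adjusted p = 0.37), with Klf4 at -1.94. Without replicate 3, 8 were lower and 3 higher, and without GFP-positive replicate 3, 3 were higher. With the replicate block 8 were higher, and 10 with the correction centred at 0. The higher members were Gadd45g, Btg2, Hsph1, Hspa8 and Hsp90aa1, and the last 2 lost their calls in 4 and 6 of 9 fits that left out a library or a number (adjusted p up to 0.169 and 0.237). The ribosomal RNA precursor Rn45s took 4.0 ± 0.15% of counts in GFP-positive and 3.24 ± 0.22% in GFP-negative libraries (SD, n = 3), and Rn45s, Malat1, Rn7sk, Rpph1, Lars2 and Gm20594 together took 10.2 ± 0.55% and 8.80 ± 0.28%.

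With the preset correlation 4 lists were higher and 12 lower; with an estimated correlation camera called 0 lists, 4 had an unadjusted p below 0.05, and fry called 21. The counts of members come from the gene-level test and do not depend on that choice. Over all 14554 tested genes 55.4% were called, with 3804 higher and 4254 lower. A count of called members near these shares does not by itself set a list apart.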

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

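The alternatives with removed abundant genes, limma-trend or a length and GC correction, and the 39 genes named outside the rule, were chosen after seeing the data. Of 150 named genes, 150 kept direction and side of the threshold with RLE scaling and without the 6 abundant genes, 149 with upper-quartile scaling and 148 without the low-count filter; of the 147 that DESeq2 tested, 146 did, as did 143 of 143 with a CPM of 1 in 3 libraries and 146 of 150 with limma-voom. Leaving out libraries or numbers kept between 135 and 143 calls. Over those fits Zic2 ran from -5.772 without GFP-positive replicate 2 to 2.551 without GFP-negative replicate 2, the libraries that hold most of its counts, and Zic1 and Pax3 likewise ran from -6.922 and -5.894 to 2.037 and 2.722, all 3 reversed there. Those fits drop 1 library of a pair and keep its partner; in each of the 3 same-numbered pairs all 3 genes were lower in GFP-positive cells, and without replicate 2 as a whole Zic1 was at -3.206 (adjusted p = 0.00316). Gene counts over fits that left out a library or a number ran from 2450 to 4169 higher and from 2951 to 4468 lower. They rose above the 3804 and 4254 of all 6 libraries without GFP-negative replicate 2 (4169 and 4468) and without replicate 2 (3988 and 4345), and fell in the other 7 fits, so fewer samples alone do not account for the range. A log2 fold change above 1 left 883 higher and 1784 lower, and glmTreat at 1.5-fold left 976 and 1844, by their stricter thresholds. The replicate block gave 3918 higher and 4422 lower, of which 3681 and 4167 were shared with the main test. Among lists and the genes named it changed the calls of the BMP and TGF-beta list (0.05583), channels (0.06386), receptor tyrosine kinase targets (0.04866), Zic2, Cd68, Hoxd3 (0.06675), Zic1 (7.87e-04), Pax3 (4.62e-04) and Col3a1 (9.74e-07), and no other call of these lists and 150 genes; members of lists that the text does not name also changed. With an estimated correlation none of the 16 called lists passed, with adjusted p of 0.2459 for precursor, astrocyte, matrix and Hox genes, 0.3023 for committed oligodendrocyte, 0.2479 for ependymal, 0.185 for neural stem, fibroblast, Wnt and interferon, 0.2585 for neuronal, 0.6209 for G2/M, 0.4409 for BMP and TGF-beta and for glycolysis, 0.4791 for cholesterol and 0.4066 for channel genes. Fry, which does not compare a list with other genes, passed mature myelin (0.0003751), microglia (0.01037), Notch (0.003774), Hedgehog (0.004076) and receptor tyrosine kinase targets (0.02221). Over the fits that left out a library or a number, adjusted p ran from 0.01434 to 0.1696 for BMP and TGF-beta, from 0.0112 to 0.0528 for channels and from 0.04896 to 0.1545 for receptor tyrosine kinase targets. With limma-trend and the block BMP and TGF-beta (0.06264) and channels (0.06347) did not pass, and with the length and GC correction neither did these (0.05676 and 0.1178) nor Hox (0.08993). With the correction centred at 0, channels (0.3804) did not pass, Hedgehog (0.03938) and receptor tyrosine kinase targets (0.02563) did, and 5588 genes were higher and 3329 lower, a split that follows from centring. Where no construction is named, the cause was not tested. Total counts of 31067850 to 45207335 leave genes below about 1 CPM with few counts, and 4856 genes had none.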

Other observations

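The gene families, and all tests in this part other than the counts over splits of the libraries, were chosen after the results were seen. Of 20 families picked by gene symbol, 7 passed camera with the preset correlation. The median of each of these 7 kept its sign with RLE and upper-quartile scaling, without the 6 abundant genes and with the length and GC correction centred at 0. Of 80 nuclear-encoded respiratory chain and ATP synthase subunits, 60 were lower and 0 higher in GFP-positive cells (median -0.39; adjusted p = 6.29e-08; adjusted p = 0.693 with an estimated correlation), for example Sdhd at -0.56 and Ndufs8 at -0.78. With the correction centred at 0, which moved the median of all genes to 0.145, this family's median was -0.152. Of 25 lysosomal genes, 20 were lower and 0 higher (median -0.77; adjusted p = 4.31e-07; adjusted p = 0.413 with an estimated correlation), for example Lamp1 at 189 ± 5.42 against 407 ± 23.5 CPM (SD, n = 3). Of 28 aldehyde dehydrogenase and glutathione S-transferase genes, 17 were lower and 1 higher (adjusted p = 5.10e-04; adjusted p = 0.413 with an estimated correlation), with Gstm1 at -3.33. Of 18 Nfi and Klf factors, 11 were lower and 3 higher (adjusted p = 0.0415; adjusted p = 0.539 with an estimated correlation), with Klf15 at -2.11. Cytosolic ribosomal protein genes gave 10 higher and 4 lower of 82 (adjusted p = 0.214).

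Families higher in GFP-positive cells were zinc finger genes, clustered protocadherins and synaptic adhesion genes. Of 366 Zfp genes, 188 were higher and 30 lower (median 0.26; adjusted p = 6.29e-08; adjusted p = 0.22 with an estimated correlation), with Zfp57, a regulator of imprinted loci, higher by 1.67. Of 55 clustered protocadherin genes, 29 were higher and 2 lower (median 0.46; adjusted p = 1.03e-05; adjusted p = 0.22 with an estimated correlation), with Pcdhb10 higher by 2.06; these genes share sequence, so counts of single members are uncertain. Of 18 synaptic adhesion genes, 14 were higher and 1 lower (adjusted p = 2.78e-04; adjusted p = 0.539 with an estimated correlation), with Slitrk1 higher by 2.35.

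Zic1, Zic2 and Pax3, dorsal patterning genes, were high in both libraries of number 315: Zic1 stood at 121 and 37.8 CPM in its GFP-negative and GFP-positive library and at 4.86 CPM or less in the other 4. Between the fractions Zic1 and Pax3 had adjusted p of 0.437 and 0.495, and 7.87e-04 and 4.62e-04 with the replicate block. Carry-over of GFP-negative cells would bring other GFP-negative genes at the Zic1 ratio of 0.313, but the astrocyte list had a median ratio of 0.1445 and an upper quartile of 0.273, which argues against it. Col3a1 (adjusted p = 0.0801, 9.74e-07 with the block) was also higher in number 315, by 50.2 CPM over the mean of the other 4 libraries. Fibroblast or meningeal cells would bring their other abundant transcripts, but the highest excess among the other 23 listed fibroblast and mural genes was 0.4812 CPM. That argues against such cells for the listed genes only. Outside that list, Nid1 stood at 33.71 and 3.429 CPM in the GFP-negative and GFP-positive library of number 315. Col14a1, a collagen gene, stood at 16.6 and 2.101 CPM there. Each value lay above the other libraries of its fraction. Of 46 tested matrix list genes, only Nid1 differed among the numbers in the fit given next. Such cells are therefore not excluded. In a fit that keeps the sorted fraction, 79 genes differed among the 3 numbers; Zic1, Zic2 and Pax3 are among them and prompted the fit, so it gives no separate support. A difference between the cultures and a difference in handling behind the numbers cannot be told apart, because the labels do not say what a number stands for.

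The higher neuronal list was set against neurons in the sort and against sequence trends. Neurons would bring their abundant transcripts together. Of the 25 members of the neuronal list other than Dcx, 8 reached 0.1 of the Dcx level of 129 CPM in GFP-positive cells, Map2 and Celf3 among them, and 17 did not (16 to 18 in the single libraries). Of those, Nefm stood at 7.25 CPM and Stmn2 at 0.217 CPM or less. However, 10 of the 17 were below the count filter and took no part in the tested shift. The list also mixes genes of different neuron types, which a given neuron need not all express. The count therefore does not decide whether neurons were the source of the whole shift. After correction for length and GC with the block the list median was 1.723, against 1.768 before (SD over members 1.05 and 1.06), which argues against those trends as the whole cause. Of the 8 members that reached the level, Gap43 was not called (0.14, edgeR adjusted p = 0.165), so it has no shift to explain. For the rest of them, neurons as the source and a program of the GFP-positive cells cannot be told apart. Nefm at 7.25 CPM and Stmn2 at 0.217 CPM or less lay far below Map2 at 4232 CPM in GFP-positive cells. How these levels stand to each other in neurons was not measured here, so the gap does not decide the source.

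G2/M genes were lower and the S phase list did not pass camera; their medians differed by -0.454 (two-sided permutation test over 38 and 34 genes, 100000 resamples, p = 1e-05, the smallest these can give; genes are not independent replicates). An error of scaling would move both lists alike, so it could not make the gap between them. The S phase median was 0.01642 with quartiles of -0.166 and 0.121, against G2/M quartiles of -0.565 and -0.253. That S phase median does not exclude a shift of both lists, which could add to the lower G2/M values. With the correction centred at 0, which moved the median of all genes to 0.145, the medians were 0.209 and -0.285, and 14 S phase genes were higher and 2 lower. The direction given for S phase genes therefore depends on that centring. RLE scaling gave 2 higher and 5 lower, and upper-quartile scaling 2 higher and 6 lower. The medians of the S phase and G2/M lists stayed apart, which a shift of whole libraries could not change. After the length and GC correction the G2/M median was -0.4306, against -0.4303 before (SD over members 0.207 and 0.21), which argues against those trends as the whole cause. A difference in cell cycle between the sorted fractions may account for it, as a hypothesis, and no effect of sorting was tested.

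The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 8058 genes by edgeR and the highest of the other splits 0. Those other splits gave 33 to 246 genes at an unadjusted edgeR p below 0.05. Of the 10 splits, 1 gave as many genes, the real split itself. Every other split mixes the fractions within its groups, so the fraction difference adds to the spread there and works against calls. The 0 therefore does not measure how many calls a random grouping would give. For gene lists, 2 of the 10 splits gave as many as the real one: it called 16 lists and the other splits 9 to 17. Each other split holds libraries of both fractions in unequal numbers, so part of the fraction difference remains between its groups. Camera with the preset correlation called lists in each of them without a called gene. Those list calls can carry that difference, so they give no rate of false calls. A list call from camera does not by itself tell the sorted fractions from mixed groups. Of the 4 splits that part all 3 numbered pairs, the real one called 16 lists and the other 3 called 10 to 14; the 6 splits that part fewer pairs called 9 to 17.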
